A study of Zea mays with 3 samples.

How the data were processed

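Small RNA was measured in 3 libraries made from anthers of field-grown maize of the inbred line W23, sorted by anther length into 1 mm, 1.5 mm and 2 mm. Per the labels, total RNA was extracted with TriReagent, adapters were ligated, and gel slices of 40 to 60 nt (insert plus adapter) were cut. Each length has 1 library, so no replicate spread exists and no test between lengths was run. All intervals below are exact 95% intervals that cover counting error only. PCR copies were not marked by molecular identifiers, so reads are not independent molecules.

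The deposited files hold raw counts: each line gives a distinct read sequence and the number of reads with it, and the values are whole numbers with no sign of normalization. The aligner, filters and software used before deposit are not given in the sources used here. The deposited sequences still carry the start of the 3' sequencing adapter. Their length is 33 nt in the 1 mm and 1.5 mm libraries and 35 nt in the 2 mm library, so the 2 mm library differs from the other two in its sequencing as well as in its length group. The adapter was recognised from the reads themselves.

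The reads were cut to the shared length of 33 nt, and the insert was taken as the part before the first exact match of the first 7 adapter bases. This fixed match length asks the same number of correct bases of every insert length. Inserts of 18 to 26 nt without an undetermined base were kept and identical inserts summed. On simulated reads, 1% of bases at every position were replaced by a base drawn at random, which could be the same base. This trimming gave 93.6% to 95.1% of these reads their true length, depending on the length, and 0.11% a wrong one. In the deposited reads, apparent miscalls were more frequent in positions 13 to 24 than in positions 1 to 12. The simulation therefore does not show that every length was recovered equally in the data. Of the deposited reads, 83.7%, 85.6% and 89.9% were kept at 1, 1.5 and 2 mm. Reads in which the adapter was not found made up 16.0%, 14.3% and 9.85%. With 1 mismatch allowed in the adapter, 51.9%, 52.3% and 57.2% of those reads also held an insert of 18 to 26 nt.

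Levels are reads per 1000000 reads of 18 to 26 nt (RPM). Shares have exact Clopper-Pearson intervals, levels exact Poisson intervals, and ratios of 2 libraries exact conditional intervals. A ratio of 2 libraries compares those libraries, not the conditions. The upper limit that a count of 0 allows was set at 3 counts.

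The following choices were made before the data were examined. Tags of 20 to 22 nt were assigned to 30 small RNA families (29 miRNA families and tasiARF, a trans-acting siRNA of the TAS3 pathway) when they held the family's core pattern, and the families were grouped into 8 lists by what they are known to regulate. A family was called higher or lower between 2 libraries by size alone, at 2-fold or more with at least 30 counts over both. Sequences with at least 100 counts over the 3 libraries together were called at 4-fold or more, with a pseudocount of 0.5 counts. A list's median log2 ratio was placed among the medians of 10000 random lists of other sequences. Each member of a random list was drawn from the 200 sequences nearest in mean level, a number set later. The text names each family with at least 30 counts over the 3 libraries, and draws on the 5 most abundant sequences of each library and, for each pair and direction, the 5 sequences with the largest fold. The part of this rule on phased loci was not applied. Any other sequence named was chosen after its values were seen.

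The fold rule was checked on simulated counts for each pair of libraries. For 2 mm against 1 mm (6580 sequences), 100% of the sequences changed by 8-fold, 0% of those changed by 2-fold and 0% of the unchanged ones passed the 4-fold rule. The share at 8-fold covers the 48 raised and 16 lowered sequences that still had at least 100 simulated counts. This minimum was taken over the simulated pair, not over the 3 libraries together. Called sequences with fewer counts in their pair were therefore not covered by the check. Both simulated libraries were drawn from the shares of 1 library with counting error only. The spread between libraries was therefore not part of this check. In a further simulation 96.0% of the intervals of a ratio held the true ratio. The counts of duplexes and of near copies were also tested on simulated data.

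Alternatives were the denominator, distinct sequences in place of reads, minimum counts, removal of the 20 most abundant sequences, thinning to equal depth, the way families were assigned, TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, and scaling to the tags of the listed families. The edgeR and DESeq2 factors were computed over the 26435 sequences with at least 30 counts, and neither tool was used for a test. Other adapter rules, the removal of near copies and random lists of 20 to 22 nt sequences were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3 were used.

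No genome sequence was used here. Phased loci, positions in the genome and fragments of annotated tRNA were therefore not analysed here, although they had been planned, and sequences other than the families are given by sequence alone. The number of annotated MIR genes per family was counted in the RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, which holds 164 miRNA genes of the inbred line B73. Signs of RNA breakdown were followed instead by the share of tags of 18 and 19 nt and by tags identical to a part of a plant 5.8S ribosomal RNA sequence, which was written from general knowledge, as were the family patterns.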

Results

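Small RNA libraries from maize anthers of 3 lengths were compared to describe how the small RNA population of the anther differs with its length. The 1 mm, 1.5 mm and 2 mm libraries held 6443578, 6273251 and 7043062 reads. After trimming, 5393322, 5367886 and 6331862 reads of 18 to 26 nt remained, in 1382961, 917742 and 775937 distinct sequences. Levels are given as RPM, reads per 1000000 reads of 18 to 26 nt. Each length was represented by 1 library, so none of the differences below has a replicate check.

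The small RNA population was a mixture of 21-nt and 24-nt tags at 1 mm and was dominated by 24-nt tags at 1.5 and 2 mm. Tags of 24 nt, the length of plant heterochromatic siRNAs and of the reproductive phased siRNAs of grass anthers, made up 46.5% of reads at 1 mm (95% interval 46.4 to 46.5), 74.8% at 1.5 mm (74.8 to 74.8) and 82.8% at 2 mm (82.8 to 82.8). Tags of 21 nt, the length of most miRNAs and trans-acting siRNAs, made up 36.7% at 1 mm, 14.2% at 1.5 mm and 6.84% at 2 mm. The 24-nt share was 1.61-fold higher at 1.5 mm than at 1 mm (1.61 to 1.61) and 1.11-fold higher at 2 mm than at 1.5 mm (1.11 to 1.11). The 21-nt share was 2.59-fold lower at 1.5 mm than at 1 mm (2.59 to 2.60) and 2.07-fold lower at 2 mm than at 1.5 mm (2.06 to 2.08).

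The other lengths were minor. Tags of 22 nt made up 10.4%, 5.97% and 4.43% of reads at 1, 1.5 and 2 mm. Tags of 23 nt made up 3.30%, 3.33% and 4.51%, and tags of 25 nt 0.730%, 0.621% and 0.450%. The 1 mm library held more short tags: 18-nt and 19-nt tags together made up 0.965% of its reads, against 0.255% at 1.5 mm and 0.308% at 2 mm. Fragments of 5.8S ribosomal RNA stood at 294 RPM at 1 mm (279 to 309), 180 at 1.5 mm (168 to 191) and 90.3 at 2 mm (83.1 to 98.1). The 2 mm library was read to 35 nt and the other two to 33 nt, so the sequencing of the 2 mm library and its anther length cannot be told apart. The 1 mm and 1.5 mm libraries, which shared the read length, gave the 1.61-fold difference in the 24-nt share.

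**Figure D1:**
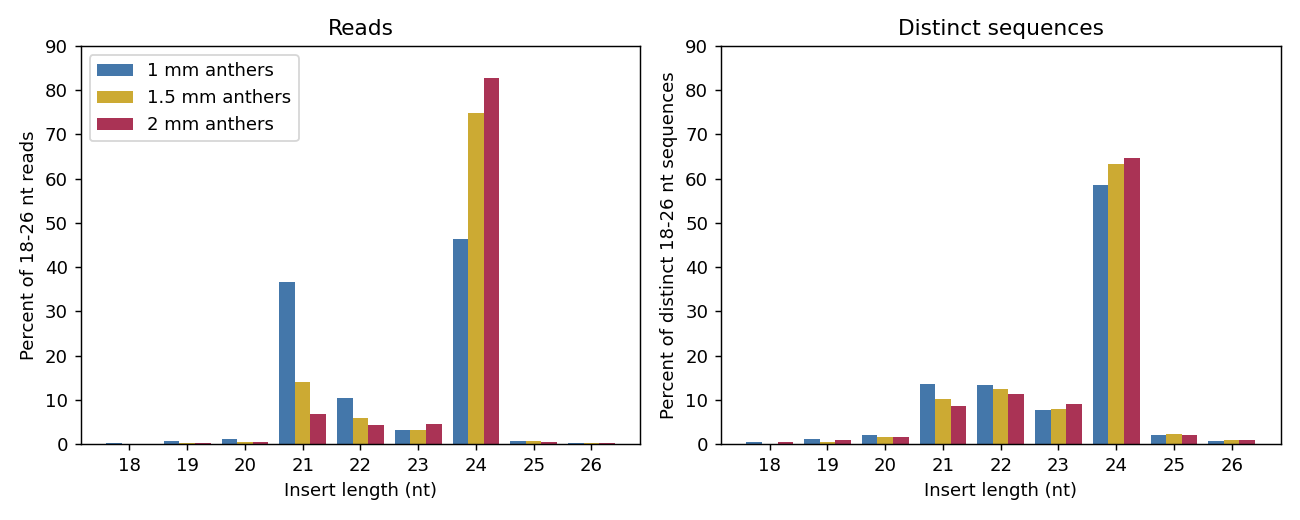
Percent of reads of 18 to 26 nt (left) and percent of distinct sequences (right) against insert length in nt, with 1 bar per library for 1, 1.5 and 2 mm anthers. The 24-nt share of reads goes from 46.5% to 74.8% and 82.8%, while the 24-nt share of distinct sequences lies at 58.7%, 63.4% and 64.6%.

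The 24-nt class was carried by fewer and more abundant sequences in longer anthers. The 100 most abundant 24-nt sequences held 24.6% of the 24-nt reads at 1 mm, 45.0% at 1.5 mm and 51.3% at 2 mm. The number of sequences that together held 50% of the 24-nt reads was 3075, 146 and 92. In a random 250000 of the 24-nt reads of each library, 110247 distinct sequences were found at 1 mm, 54539 at 1.5 mm and 39809 at 2 mm. The 144 sequences of 24 nt with at least 10000 counts over the 3 libraries held 12.6%, 37.2% and 46.3% of all reads. Counts over the 3 libraries together give more weight to the 1.5 and 2 mm libraries, which held more 24-nt reads (4015109 and 5242829, against 2505649 at 1 mm), so these bins favour sequences that were high there. In contrast, the 1579854 sequences of 24 nt with at most 10 counts over the 3 libraries held 17.4%, 11.9% and 8.93%. Distinct sequences include miscalled reads, so these counts are upper values.

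**Figure D2:**
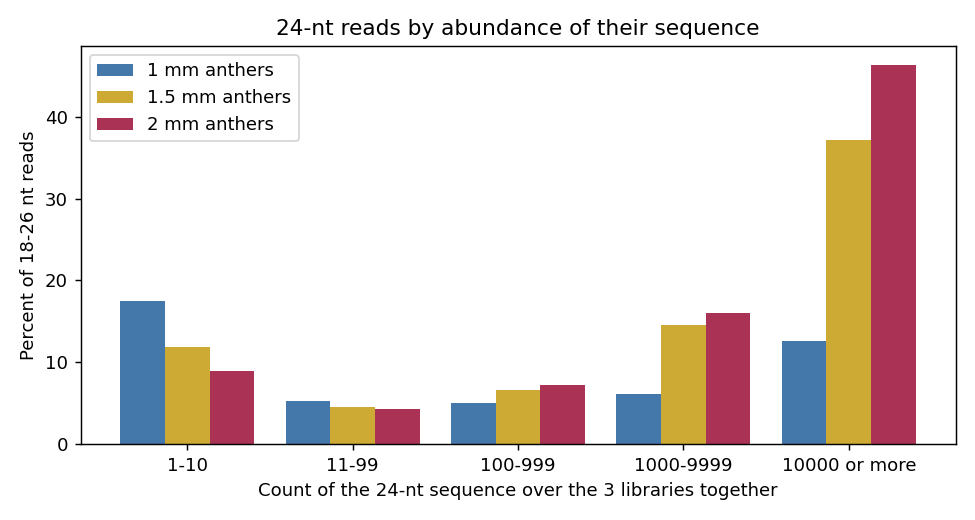
Percent of all reads of 18 to 26 nt held by 24-nt sequences, with the sequences binned by their count over the 3 libraries together, and 1 bar per library for 1, 1.5 and 2 mm anthers. The most abundant bin goes from 12.6% to 46.3% while the rarest goes from 17.4% to 8.93%.

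The same 24-nt sequences led the longer anthers. ATGGAGAGTAGAAGACAAACTCTT, the most abundant sequence at 1.5 and 2 mm, stood at 7221 RPM at 1 mm (7149 to 7293), 27080 at 1.5 mm (26941 to 27219) and 48340 at 2 mm (48169 to 48512), a 6.69-fold difference between 1 and 2 mm. TCATGACTGAGCATACATTGACTT stood at 6974, 22398 and 33886 RPM. TTTCACATGTAGAATTGAGGGCAT stood at 5330, 18429 and 26351, and TCAGGAAGTAGAAGGTGCAGCCAC at 5331, 19307 and 18879. AAGATATGATTCTTCTCGTCGAAC stood at 3487, 10123 and 11557, and AGAGAATTCCTGATGAAGATTTGC at 3132, 8664 and 11597. The most abundant sequence at 1 mm was the 21-nt AGAAGAAATCATGGACATCAA, with 13370 RPM (13272 to 13468), which was 6.60-fold lower at 2 mm (2026 RPM). The 21-nt TCCGGAATGTAACAATTGGTA was 5.35-fold lower at 2 mm than at 1 mm. The genes of these sequences were not analysed here.

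The 100 most abundant 21-nt sequences held 39.3%, 39.7% and 37.2% of the 21-nt reads at 1, 1.5 and 2 mm, and 206, 207 and 268 sequences held 50% of them. Of the 22-nt reads, the 100 most abundant sequences held 13.8%, 18.4% and 24.7%, and 6361, 4188 and 1798 sequences held 50%. The first nucleotide, which sorts plant small RNAs between Argonaute proteins, was A in 44.4% of 24-nt reads at 1 mm (44.3 to 44.4), 39.1% at 1.5 mm and 38.9% at 2 mm, and U in 27.7%, 30.9% and 31.5%. Over distinct 24-nt sequences U came first in 21.9%, 21.7% and 22.3%. Among 22-nt reads, U came first in 39.9%, 36.1% and 34.8%. Among 21-nt reads, U came first in 31.8%, 31.7% and 32.6%.

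Of the 30 listed small RNA families, 18 had at least 30 counts over the 3 libraries. The most abundant was miR168, which targets the Argonaute gene AGO1, followed by miR166, which targets HD-ZIP III transcription factors that set organ polarity. miR168 stood at 6255 RPM at 1 mm (6188 to 6322), 3675 at 1.5 mm (3624 to 3727) and 1783 at 2 mm (1751 to 1816), and 99.3% of its tags were TCGCTTGGTGCAGATCGGGAC. miR166 stood at 2570, 1293 and 714 RPM. Their loci number 2 and 13 annotated MIR genes in B73, so the values are sums over near-identical copies. No tag was found for miR395, miR397, miR398, miR399, miR1432 or miR482, which allows up to 0.556, 0.559 and 0.474 RPM at 1, 1.5 and 2 mm.

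Between 1 and 1.5 mm, 7 of the 18 families were at least 2-fold lower at 1.5 mm and none was 2-fold higher. The 21-nt share was itself 2.59-fold lower. With TMM, DESeq2 or family scaling 2 families were at least 2-fold lower, and no ratio of the 7 changed sign. In the auxin list (4 families measured), miR167, which targets auxin response factors, was 2.25-fold lower (1.98 to 2.55) and tasiARF, which also targets auxin response factors, 2.39-fold lower (1.67 to 3.46). miR164 and miR390 differed by less than 2-fold. In the growth and polarity list (4 measured), miR444 was 3.50-fold lower (2.26 to 5.59) and miR394 had 67 counts at 1 mm and 1 at 1.5 mm, a ratio of 66.7 (11.6 to 2673). miR394 was read as a single 20-nt tag, and the 20-nt share was itself 2.13-fold lower at 1.5 mm. In the nutrient and stress list (3 measured), miR169 was 2.17-fold lower (1.46 to 3.28), while miR827, which targets phosphate transporters, stood at 144 and 148 RPM. In the phase change list (3 measured), miR529 was 2.01-fold lower (1.61 to 2.51), and miR156 and miR172 differed by less than 2-fold. Of the triggers of phased siRNAs, miR2275, which triggers 24-nt phased siRNAs in grass anthers, was 2.23-fold lower (1.82 to 2.74), and miR2118, which triggers the 21-nt ones, stood at 7.23 and 4.28 RPM with overlapping intervals.

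Between 1.5 and 2 mm, 8 of the 18 families were at least 2-fold lower at 2 mm and 1 was higher. The 21-nt share was itself 2.07-fold lower. The number lower was 2 with TMM, 1 with DESeq2 and 0 with family scaling, and no ratio of the 9 changed sign. With family scaling, however, the log2 ratios of miR169, miR168 and miR164 were -0.0062, -0.036 and -0.060, so their direction was not settled. miR156, which targets SPL transcription factors, was 3.84-fold lower (3.32 to 4.45) and miR529, which targets the same class of genes, 3.32-fold lower (2.34 to 4.80). miR167 was 2.76-fold lower (2.28 to 3.36), miR164 2.11-fold lower (1.35 to 3.33), miR168 2.06-fold lower (2.01 to 2.11), miR2275 2.28-fold lower (1.70 to 3.07), miR827 2.27-fold lower (2.01 to 2.56) and miR169 2.04-fold lower (1.17 to 3.62). miR159, which targets the GAMYB genes of anther development, was 2.09-fold higher, with 13 and 32 counts (1.07 to 4.33), but less than 2-fold higher by its single listed sequence or by tags of 18 to 26 nt. miR390 was 1.55-fold higher (1.08 to 2.26). miR394 and miR2118 had fewer than 30 counts over these libraries.

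Between 1 and 2 mm, 14 of the 18 families were at least 2-fold lower at 2 mm and none was 2-fold higher. The 20, 21 and 22-nt shares were themselves 2.79-, 5.37- and 2.34-fold lower, so these calls include the fall of whole size classes. With TMM, DESeq2 and family scaling, 9, 4 and 2 were lower and 2, 3 and 4 higher. The growth and polarity list had 4 of 4 measured families lower, with miR166 3.60-fold lower (3.48 to 3.72), miR394 11.2-fold lower (5.16 to 29.0), miR444 4.13-fold lower (2.67 to 6.59) and miR171 2.50-fold lower (1.32 to 4.98), which turned with DESeq2 and family scaling. With family scaling the log2 ratios of miR166, miR394, miR444 and miR171 were -0.03, -1.59, -0.21 and 0.51. In the auxin list 3 of 4 were lower, with miR167 at 6.20-fold (5.22 to 7.41), tasiARF at 4.09-fold (2.72 to 6.31) and miR164 at 2.92-fold (1.93 to 4.51, turned with family scaling), while miR390 stood at 15.2 and 13.9 RPM. In the phase change list miR529 was 6.67-fold lower (4.83 to 9.41) and miR156 4.90-fold lower (4.26 to 5.66). miR172, which targets AP2-type transcription factors and in plants moves opposite to miR156, stood at 22.3 and 28.4 RPM, a ratio of 1.28 (1.01 to 1.62). Both triggers of phased siRNAs were lower, miR2118 by 9.16-fold (3.61 to 29.8, 39 and 5 counts) and miR2275 by 5.07-fold (3.91 to 6.65). In the nutrient and stress list miR169 was 4.43-fold lower (2.74 to 7.45) and miR827 2.21-fold lower (1.96 to 2.49), which turned with DESeq2 and family scaling, and miR528 stood at 7.79 and 4.74 RPM. miR168, the measured member of the silencing machinery list, was 3.51-fold lower (3.43 to 3.58). miR159, the measured member of the anther MYB and TCP list, stood at 3.71 and 5.05 RPM.

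**Figure D3:**
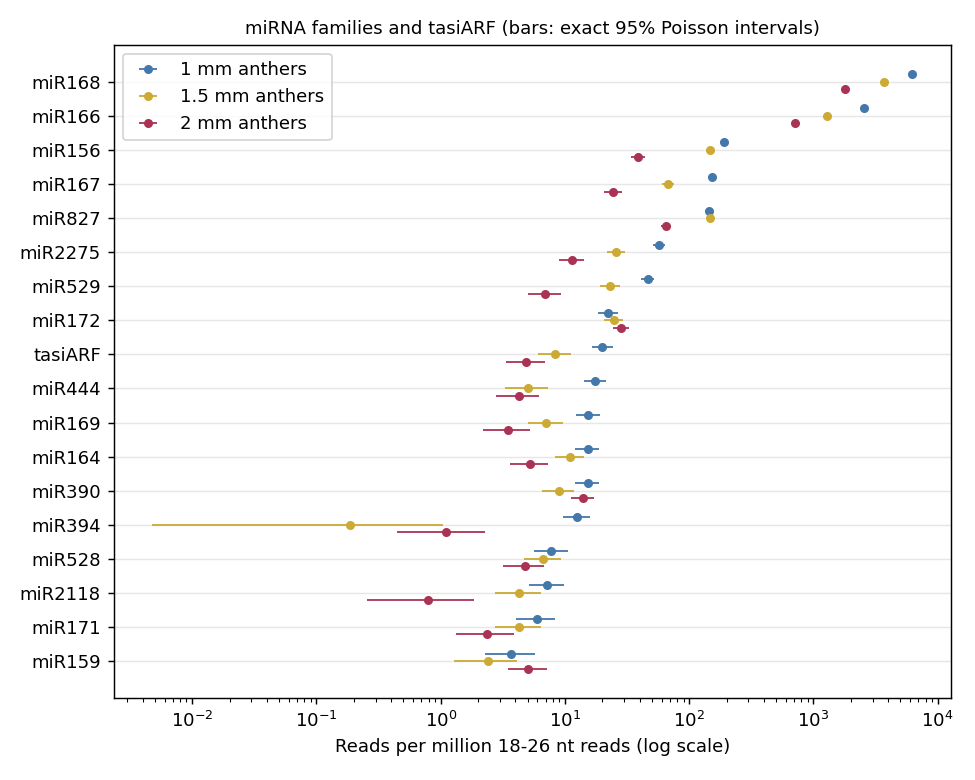
RPM (log scale) of the 18 families with at least 30 counts, for the 1, 1.5 and 2 mm libraries, with exact 95% Poisson intervals. miR168 lies at 6255 and 1783 RPM at 1 and 2 mm (a log2 ratio of 0.0034 when scaled to the listed families, of which it is the most abundant), miR166 at 2570 and 714, and miR172 at 22.3 and 28.4.

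The 18 families had a median log2 ratio of -1.93 at 2 mm over 1 mm, at percentile 18.98 of random lists of sequences of all lengths matched on level. Among random lists of 20 to 22 nt sequences, whose median was -2.47, the percentile was 99.5. The families were thus lower by less than most lists of sequences of their own lengths. The medians of the lists with at least 3 measured families were -2.29 for phase change, -1.77 for auxin, -1.94 for growth and polarity and -1.14 for nutrients and stress (percentiles 22.7, 31.0, 26.8 and 44.5 among lists of all lengths, and 69.2, 90.5, 85.8 and 94.9 among those of 20 to 22 nt). At 2 mm over 1.5 mm the phase change list had a median of -1.72, at percentiles 1.84 and 4.36. With 3 measured families this median is the value of miR529 alone. For the same pair the percentiles were 25.57 and 70.25 for auxin, 51.93 and 91.33 for growth and polarity, and 25.77 and 60.05 for nutrients and stress. At 1.5 mm over 1 mm the median of the 18 families was -0.76 (percentiles 26.2 and 99.9), and at 2 mm over 1.5 mm -0.93 (10.1 and 84.6). The calls depended on the scaling. TMM factors raised the level at 2 mm relative to 1 mm by 1.00 on the log2 scale, and 9 families were then at least 2-fold lower and 2 higher. Relative to the sum of the listed families, 2 were at least 2-fold lower, and 4 (miR172, miR159, miR390 and miR528) at least 2-fold higher. The log2 ratios of miR164, miR171 and miR827 were then 0.28, 0.51 and 0.67, and that of miR168, the largest part of this sum, was 0.0034. The other 10 of the 14 families (miR156, miR529, miR167, tasiARF, miR166, miR394, miR444, miR2118, miR2275 and miR169) had a ratio below 1 under every alternative in which they were measured, although with family scaling that of miR166 was -0.03 on the log2 scale and 2 of them (miR394 and miR2118) were at least 2-fold lower. The library with the highest level of most families, 1 mm, also held the most 5.8S ribosomal RNA fragments (294 RPM, against 180 and 90.3). Levels of tags of other lengths fall as the 24-nt share rises. All reads that are not 24 nt stood at 0.471 times the 1 mm share at 1.5 mm and 0.321 times at 2 mm. Tags of 18 and 19 nt, the other sign of breakdown, made up 0.965%, 0.255% and 0.308% of reads. From 1.5 to 2 mm this share rose while the 5.8S fragments fell, so the signs did not go together. Whether RNA breakdown differed between the libraries is not settled by these values.

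Among 9168 sequences with at least 100 counts over the 3 libraries, 693 were at least 4-fold higher and 410 at least 4-fold lower at 1.5 mm than at 1 mm. At 2 mm against 1.5 mm, 314 were higher and 490 lower, but 222 of the 314 lay within 2 mismatches of a sequence at least 20 times as abundant, and 92 were left without them. At 2 mm against 1 mm, 1743 were higher and 3703 lower, of which 413 and 76 were such near copies. The split differed by length. At 2 mm against 1 mm, 2135 of 2486 sequences of 21 nt were lower and 41 higher. The 21-nt share was itself 5.37-fold lower, which is beyond the 4-fold rule, so these calls largely restate that share. Of the 4850 sequences of 24 nt, 1276 were higher and 990 lower, so the 4-fold calls went both ways. The median ratio of these 4850 sequences was 2.67, and the 24-nt share was itself 1.78-fold higher. The minimum count over the 3 libraries together favours 24-nt sequences that were high at 1.5 and 2 mm. Of 1072 sequences of 22 nt, 123 were higher and 427 lower, and of 519 sequences of 23 nt, 280 were higher and 39 lower. At 2 mm, 37.6% of the 23-nt reads equalled a more abundant 24-nt sequence without its last base, and 38.5% one without its first. At 1 mm these shares were 26.9% and 17.3%, so the 23-nt calls are not separate from the 24-nt class. The split into higher and lower depended on the scaling. Higher calls made up 62.8%, 39.1% and 32.0% of the calls in the order given above, and 95.6%, 73.7% and 76.9% with TMM factors.

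The 24-nt TTACACTGGTGCTTTAAAATAGTA, at rank 4 by fold among the sequences higher at 1.5 mm than at 1 mm, was 24.3-fold higher at 1.5 mm (20.9 to 28.4), with 178, 4307 and 372 counts at 1, 1.5 and 2 mm. The 18-nt GCGTTTGTAGTCCAACGG was 153-fold lower at 1.5 mm than at 1 mm (59.4 to 563), with 614, 4 and 66 counts, and the 18-nt share was itself 8.06-fold lower. The 23-nt AGGTGTAGGATAAGTGGGAGCCT had 117 counts at 1.5 mm and 1 at 2 mm, a ratio of 138 (24.3 to 5497). The 25-nt GATTTATGAAAGACGAACAACTGCG had 230 counts at 1 mm and 0 at 2 mm, a difference with a lower 95% limit of 72.6-fold. The 21-nt AGAAGCTGGGAATGACTTAGG had 156 counts at 1 mm and 0 at 2 mm, with a lower limit of 49.1-fold. The 24-nt GACGGCTGGACTCACTCGATGCCT had 0, 24 and 414 counts, higher at 2 mm than at 1 mm with a lower limit of 95.2-fold. It and the other 4 sequences with the largest folds among those higher at 2 mm than at 1 mm each lay within 2 mismatches of a sequence at least 20 times as abundant in the 2 mm library.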

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

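Some reads outside the measured range exceeded the limit that a count of 0 allows (3 reads); no control library exists to compare them with. Reads made of A alone numbered 8143 at 1 mm, 31651 at 1.5 mm and 930 at 2 mm. Inserts of 14 to 17 nt numbered 13625, 1644 and 5580, so the 1.5 mm library held the fewest short inserts here as it did at 18 nt. Adapters with no insert numbered 4568, 3295 and 4018. Inserts of 27 to 28 nt, which only the longer reads of the 2 mm library can show, numbered 4470.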

How the results depend on the processing

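With 1 library per length no replicate could be left out. No paired analysis was possible because each length has a single library and the labels give no replicate numbers. The alternatives that need a genome or annotated rRNA and tRNA sequences (genome-matched tags, structural RNA, phased loci, genome features) were not run. The adapter rules and the removal of near copies were added after seeing the data. The 24-nt share was higher in the longer anthers of each pair, and the 21-nt and 22-nt shares lower at 2 than at 1 mm, under each alternative run. Their sizes moved, and the cause was not tested. In the order all tags in the file, distinct sequences, at least 5 counts, without the 20 most abundant sequences, whole adapter exact and whole adapter with 1 mismatch, the 24-nt ratio of 1.5 over 1 mm was 1.65, 1.08, 1.81, 1.58, 1.59 and 1.58. For 2 over 1.5 mm it was 1.16, 1.02, 1.11, 1.11, 1.11 and 1.10, and for 2 over 1 mm 1.91, 1.10, 2.01, 1.76, 1.76 and 1.74. The 21-nt ratio of 2 over 1 mm was 0.200, 0.647, 0.151, 0.228, 0.174 and 0.187, and the 22-nt ratio 0.459, 0.845, 0.397, 0.525, 0.402 and 0.434. Thinning to equal depth left these ratios within their counting intervals. The difference in 5' A among 24-nt tags between 2 and 1 mm, -5.44 percentage points by reads, was -3.28 by distinct sequences. Families at least 2-fold lower at 1.5 than at 1 mm numbered 4 by the single listed sequence (14 families measured), and 2 with TMM, with DESeq2 and with family-tag scaling. At 2 over 1.5 mm the families lower numbered 2, 1 and 0 under these 3 scalings and the families higher 2, 2 and 3, while the single listed sequence and tags of 18 to 26 nt gave 0 higher. At 2 over 1 mm the families lower numbered 9, 4 and 2 and the families higher 2, 3 and 4. Among the families called at 2 over 1 mm, log2 ratios that changed sign were miR164 (0.28), miR168 (0.0034), miR171 (0.51) and miR827 (0.67) with family-tag scaling, where miR168 is the largest part of the sum and its value is close to 0, and miR171 (0.11) and miR827 (0.27) with DESeq2 size factors. Among those not called, miR528 (-0.71) went to 0.29, 0.70 and 1.10 with TMM, DESeq2 and family-tag scaling, and miR390 (-0.13) to 0.87, 1.28 and 1.68, and to 0.0014 by the single listed sequence. Sequences called higher and lower at 1.5 over 1 mm numbered 2160 and 2033 with at least 30 counts, 44 and 54 at 8-fold, and 2204 and 102 with TMM. At 2 over 1.5 mm they numbered 1133 and 2637, 113 and 84, and 486 and 173; without near copies 92 of the 314 higher ones were left. At 2 over 1 mm they numbered 4558 and 10980, 560 and 1133, and 3768 and 1133. Fewer or more sequences pass a changed minimum or fold by construction; a scaling shifts every ratio by 1 factor. Depth limits the families with under 100 counts over the 3 libraries, miR159, miR171, miR394 and miR2118, whose intervals are wide.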

Other observations

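All tests of explanations in this part were chosen after the results were seen. Both main size classes carried the mark of duplexes cut with 2-nt 3' overhangs. Among distinct 21-nt sequences, ordered pairs whose first 19 nt were reverse complements of each other numbered 24648, 10634 and 7388 at 1, 1.5 and 2 mm, which is 2.90, 3.46 and 3.38 times the mean of the counts at 18 and 20 nt. Among 24-nt sequences, pairs at 22 nt numbered 27550, 35056 and 42434, or 1.62, 2.27 and 2.40 times the mean at 21 and 23 nt. The number of 24-nt reads was not matched between the libraries in these counts. The 22-nt class showed no such excess at 1 and 1.5 mm (0.942 and 1.02 times) and a small one at 2 mm (1.12 times). Per 1000 distinct sequences with at least 5 counts, 24-nt pairs numbered 93.9, 204 and 265, and 21-nt pairs 192, 152 and 123. At this minimum the 24-nt pairs were 4.29, 4.99 and 4.55 times the mean at the neighbouring overlaps, with no steady order over the lengths, and the 21-nt pairs 6.26, 8.77 and 11.5 times.

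Within miR2275, the variants TTCAGTTTCCTCTAATATCTCA (188, 85 and 45 counts) and TTTGTTTTCCTCCAATATCTCA (118, 53 and 27) kept similar proportions over the 3 lengths. Of the 9168 sequences with at least 100 counts, 12 were at least 4-fold higher at 1.5 mm than at both other lengths and 11 at least 4-fold lower. Of the 12, 9 lay within 2 mismatches of a sequence at least 20 times as abundant. The other 3 of the 12 were TTACACTGGTGCTTTAAAATAGTA, TCGTTGAGCGCAACACAACATGGC (115, 632 and 113 counts) and AGGTGTAGGATAAGTGGGAGCCT. Of the 23-nt reads, 26.9%, 39.5% and 37.6% at 1, 1.5 and 2 mm equalled a more abundant 24-nt sequence of the same library without its last base, and 17.3%, 24.2% and 38.5% one without its first base.

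The first pattern is the higher 24-nt share in longer anthers. A gel slice cut toward longer inserts would raise the 25-nt share as well, but relative to 1 mm that share was 0.850 times as high at 1.5 mm (0.838 to 0.863) and 0.616 times at 2 mm (0.607 to 0.626), which argues against the slice as the whole cause. Other lengths go partly with a slice: at 1.5 mm the 26-nt share was 1.18 times as high (1.152 to 1.203), below the 1.61 of 24 nt, and the 18, 19 and 20-nt shares were 0.124, 0.331 and 0.469 times, so a part of the difference may still come from it. Better recovery of every 24-nt molecule would move all sequences of this length by 1 factor. At 2 mm against 1 mm, however, 990 of 4850 were at least 4-fold lower while 1276 were at least 4-fold higher (94 and 529 at 1.5 mm against 1 mm). In addition, 250000 of the 24-nt reads held 0.495 times as many distinct sequences at 1.5 mm as at 1 mm. These values argue against better recovery as the whole cause at both lengths. A different run of the 2 mm library has no part in the 1.61-fold difference between the 1 and 1.5 mm libraries, which leaves that library out. Its part in the 2 mm share cannot be told apart from anther length. A difference between anther lengths and a difference between single libraries cannot be told apart with 1 library per length, and both stay open.

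The second pattern is the lower level of 21-nt tags and of most listed families at 2 mm. Dilution by the 24-nt class alone would lower every other tag by the same factor, to 0.321 times the 1 mm level, the ratio of all reads that are not 24 nt. The intervals of 13 of the 18 families left this value out, 8 below it (miR394 at 0.0890 and miR2118 at 0.109 the lowest) and 5 above it (miR172, miR159, miR390, miR528 and miR827), and the 21-nt class stood at 0.186 and the 22-nt class at 0.428. These intervals cover counting error only, and the spread between libraries was not measured. Dilution may still set part of each difference, and a change with anther length cannot be told apart from a difference between libraries with 1 library per length.

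The third pattern is the set of sequences that were higher at 2 mm. Of the 314 sequences at least 4-fold higher at 2 mm than at 1.5 mm, 70.7% lay within 2 mismatches of a sequence at least 20 times as abundant, against 6.93% of the sequences that moved less than 4-fold, which is consistent with miscalled bases in reads of abundant sequences. The near copies differed from the abundant sequence only in positions 13 to 24 in 98.2% of cases, which argues against related loci as their source, and 48.9% of the mismatches were G-to-C changes. In single-mismatch copies of the 100 most abundant 24-nt sequences, G-to-C changes in positions 13 to 24 occurred at 467 per 100000 bases at 2 mm, against 64.4 at 1 mm and 57.8 at 1.5 mm. Other changes in these positions were lower at 2 mm, such as G-to-T at 198, against 453 and 401. The profile of changes thus differed between the libraries. Most near copies (209 of 222) also had 1 mismatch, so these rates are not separate support for miscalls. Of the 1743 sequences at least 4-fold higher at 2 mm than at 1 mm, 23.7% were near copies by the same rule. Miscalled copies of another length, with more mismatches or of less abundant sequences would be missed. Miscalls of these kinds are therefore not excluded for the rest.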
